A study of Mus musculus with 2 samples.

How the data were processed

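Histone H3 acetylated at lysine 9 (H3K9ac), a mark of active start sites and enhancers, was profiled by ChIP-seq in hearts dissected from mouse embryos of the B6NCrl strain at embryonic day 13.5. Per the labels, the hearts came from pooled male and female embryos. The series holds 1 group of 2 biological replicates, called replicate 1 and replicate 2 here, and no second tissue, age or mark. The comparisons are therefore between the replicates and between places in the genome.

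The authors deposited 4 peak lists in narrowPeak format on the mm10 build. Per the text files deposited beside them, the list of replicate 1 was derived from its filtered alignment and 2 further input files, and the list of replicate 2 from its filtered alignment and 1 of those same files. The pooled list was derived from both alignments and both further files, and the replicated list from the other 3 lists. The further files are not described there; the labels name a control experiment. The peak caller, its version, its settings and the rule that made the replicated list are not given in the sources used here. The deposited values of each peak are a fold enrichment, which is the ratio of the signal over its background, a −log10 p-value, a −log10 q-value, and the summit position counted in bases from the peak start. All fold enrichments, p-values and q-values of single peaks in the text are the authors' values, and they were used within a list: to describe, rank or filter peaks and, in the closing section, to compare the folds of groups of genes. The smallest deposited −log10 p was 2.03 in replicate 2 and the pooled list and 2.04 in replicate 1, so the lists hold weak as well as strong peaks.

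Read counts were not used here, so the sequencing depth of each library is unknown. Shares of peaks are given with exact (Clopper-Pearson) 95% intervals where an interval is printed; these cover counting error only. Values of each replicate list are given as mean ± SD (n = 2), and values of the pooled and replicated lists have no replicate error.

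Genes, transcripts and exons were taken from GENCODE vM21 on GRCm38, the assembly that mm10 is built from, and sequence, assembly gaps and repeat masking from the GRCm38.p6 genome. Peaks on the 21 placed chromosomes were used; 9 peaks of each list on scaffolds not placed on a chromosome were left out. Coordinates are printed counting from 1. Genes were the 21938 protein-coding genes of the placed chromosomes, and a gene had a start-site peak when a peak overlapped the 1000 bp on either side of any of its annotated transcription start sites. Such a gene is called marked. The covered length of a gene is the number of bases under peaks within 5000 bp on either side of a start site, taken at the start site with the most, so that it can reach 10001 bp. Distal peaks lay more than 2500 bp from every annotated start site of any gene, and were counted per gene within 50 kb of its start sites.

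Peaks of the replicate lists were called overlapping when they shared at least 1 bp. Chance levels came from 100 random placements of a list within its chromosomes (bedtools shuffle, fixed seeds). For genomic features each summit was assigned to the first of start site (within 1000 bp), exon, intron and between genes that held it. Overlap by strength was read in 10 bins of each list ranked by fold enrichment.

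A set of 18 gene lists was fixed before the data were examined. So were the tests, the gene-naming rule and all but 2 of the alternatives. The direct test of anterior against posterior Hox genes was not among the tests so fixed. The lists hold genes of the sarcomere, cardiac transcription factors, calcium handling and ion channels, other cardiomyocyte genes, heart development signalling, endothelium and endocardium, epicardium and mesenchyme, smooth muscle and pericyte, blood, neural and neural crest, skeletal muscle, liver, lung and gut endoderm, pluripotency and germ line, anterior Hox genes (paralogues 1 to 5), posterior Hox genes (paralogues 9 to 13), cell cycle, housekeeping, and all olfactory receptor genes. Heyl is a member of 2 of the lists. The share of marked members was tested against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. The median covered length and the median number of distal peaks of each list were set against 10000 random lists of as many protein-coding genes and given as a percentile; lists outside the 2.5 to 97.5 range are called above or below it. Genes of 1 library are not replicates of one another, so these p-values and percentiles describe the libraries at hand.

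The rule for named genes took the 10 genes with the longest covered length (ties broken by the fold of the strongest start-site peak), the 10 genes with the strongest start-site peak, the longest-covered pair of each list with up to 2 unmarked members in alphabetical order, up to 5 list members marked in 1 replicate list and not the other, and the 5 strongest distal peaks. Genes named outside the rule are said to be so.

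The alternatives were a reciprocal overlap of 50%, an overlap of 50% of the peak, a −log10 q of at least 5, the stronger part of each list above its median fold, lists cut to equal numbers, each replicate list alone, the pooled list, a start-site window of 2500 bp, the outermost 5′ end of each gene alone, a covered-length window of 10000 bp, a distal reach of 100 kb, and comparison within marked genes. Genes were also matched on 10 bins of the CpG observed/expected ratio within 500 bp of the gene's outermost 5′ end (exact Cochran-Mantel-Haenszel test or matched random lists). That end need not be the start site with the peak, so matching on CpG can miss the marked site. A further alternative matched on 10 bins of the number of start sites within 500 kb of that end. The 2 alternatives added after seeing the data were random placement without assembly gaps and a start-site call that needed the summit of the gene's strongest peak to lie nearest to its own start site.

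The interval arithmetic was checked against brute force with 0 mismatches. The tests were run on simulated data with lists of 20 genes. The Fisher test called 600 of 600 lists with 100% of members marked, 569 of 600 with 25% marked (94.8%), and 38 of 2400 unchanged lists (1.58%). The covered-length percentile called 13 of 20 lists whose lengths were doubled and 0 of 20 unchanged ones, so a doubling can be missed at this list size. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, bedtools 2.31.1 and R 4.3.3 were used.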

Results

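H3K9ac peaks were mapped in the heart of the mouse embryo at day 13.5, in 1 group of 2 biological replicates of pooled hearts. The list of replicate 1 held 118783 peaks covering 64.3 Mb (median width 285 bp), and that of replicate 2 held 91385 peaks covering 51.7 Mb (median width 299 bp). The mean number was 105084 ± 19373 peaks (SD, n = 2) and the mean covered length 58.0 ± 8.95 Mb. The pooled list held 123145 peaks over 75.9 Mb. The replicated list, on which most values below rest, held 69835 peaks over 63.1 Mb, with a median width of 570 bp, 6979 peaks wider than 2 kb and a share of 2.32% of the placed chromosomes. Read counts were not used here, so the depth behind the lists is unknown.

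The first comparison asks which genes and peaks recurred between the replicates. A start-site peak lay at 14726 of 21938 protein-coding genes in both replicate lists, at 547 genes in replicate 1 alone and at 178 in replicate 2 alone. Of the genes marked in either replicate, 95.3% were marked in both. Every member of the sarcomere (22 genes), cardiac transcription factor (27), other cardiomyocyte (20), signalling (26) and endothelial (20) lists was marked in both replicates. Most list members that differed between the replicates belonged to the blood, neural, skeletal muscle, endoderm and germ line lists. Of these, 6 of 20 neural genes were marked in replicate 1 alone, as were 4 of 20 blood genes. Snap25, a synaptic vesicle fusion protein, Tubb3, a neuronal tubulin, Rgs5, a pericyte regulator of G-protein signalling, and Apoa1, a liver apolipoprotein, were marked in replicate 1 and not in replicate 2. Sftpc, a lung surfactant protein, was marked in replicate 2 alone. Their start-site peaks in the replicated list had folds of 3.78 at Snap25, 3.14 at Tubb3, 3.10 at Rgs5 and 2.97 at Apoa1, and of 29.3 at Sftpc, where the summit was nearer to Bmp1.

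Peak by peak, 61457 replicate 1 peaks overlapped a replicate 2 peak (51.7%, exact 95% interval 51.5 to 52.0). In the other direction 66114 replicate 2 peaks had a partner (72.3%, 72.1 to 72.6). Random placement gave 4.14% ± 0.0662 and 5.33% ± 0.081 (SD over 100 placements). The lists shared 41.2 of the 74.8 Mb that either covered (55.1%). In the strongest of 10 rank bins all 11879 peaks of replicate 1 had a partner, and so did all 9139 peaks of replicate 2. In replicate 1 the share was 77.6% in bin 3, 44.0% in bin 5 and 24.7% in bin 10, the weakest. In replicate 2 it was 96.8% in bin 3, lowest in bin 9 (45.1%) and 53.3% in bin 10. The 57326 peaks of replicate 1 without a partner had a median width of 214 bp and a median fold of 2.86, and made up 21.9% of its covered bases. For the 25271 peaks of replicate 2 without a partner these values were 199 bp, 2.81 and 10.9%. The share with a partner depends on how much overlap is asked for: with at least 50% of both peaks it was 34.5% for replicate 1 and 44.8% for replicate 2.

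**Figure D1:**
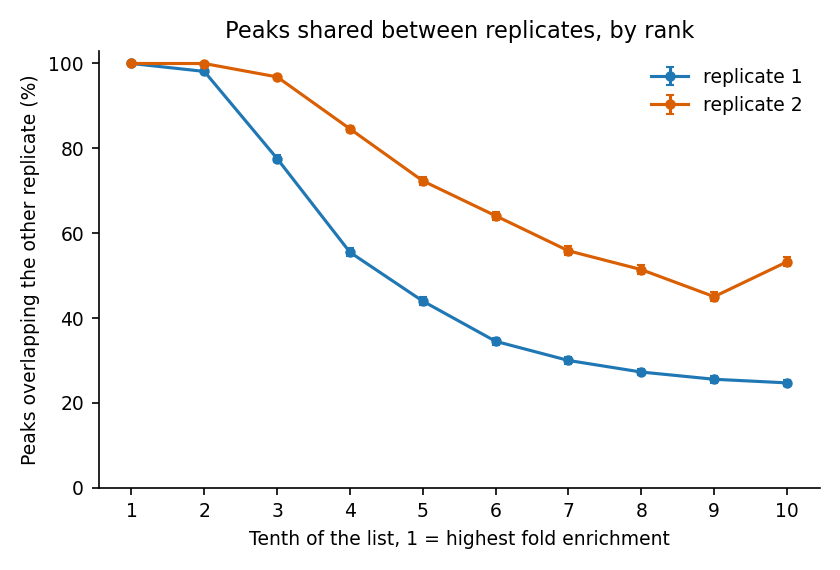
Share of peaks (%) with an overlapping peak in the other replicate, in 10 equal bins of each list ranked by fold enrichment, strongest first, with exact 95% intervals. Both lists start at 100%; replicate 1 ends at 24.7%, and replicate 2 is at 45.1% in bin 9 and 53.3% in bin 10.

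The replicated list was a subset of the pooled list. All of its peaks were identical in coordinates to a pooled peak, and they were 56.7% of the pooled peaks. The strongest of 10 rank bins of the pooled list was kept whole, bin 5 kept 64.4% and bin 10 kept 12.9%. Replicate 1 overlapped 92.0% of the replicated peaks, replicate 2 overlapped 84.1%, both together 77.7%, and 1140 peaks (1.63%) overlapped neither list. With at least 50% of the replicated peak overlapped, both replicates covered 53.2% of the list and neither covered 9.20%.

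The second comparison asks where in the genome H3K9ac lay. Start sites held 24368 of 69826 replicated summits (34.9%), 5.58 times the share under random placement (6.26% ± 0.0916, SD over 100 placements). Exons away from start sites held 5.62% (1.68 times chance) and introns 41.4% (1.05 times chance). The space between genes held 18.1%, which was 0.356 times chance. In the replicate lists, start sites held 29.8% ± 3.94 of summits, exons 6.08% ± 0.392, introns 45.1% ± 2.45 and the space between genes 19% ± 1.11 (SD, n = 2). Peaks within 1 kb of a start site numbered 26089, with a median width of 1122 bp, a median fold of 8.0 and 37.3 Mb covered. The 35834 distal peaks were narrower and weaker, with a median width of 456 bp, a median fold of 3.04 and 21.1 Mb covered. In the stronger part of the replicated list, above its median fold, the share at start sites was 55.4%.

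The third comparison asks which genes carried H3K9ac at their start sites. Genes of the heart muscle were marked almost without exception. All 22 sarcomere genes were marked against 67.8% of other protein-coding genes (adjusted exact p = 0.000924), all 27 cardiac transcription factors (adjusted p = 0.000339), and all 20 other cardiomyocyte genes (adjusted p = 0.00103). Of the 22 genes of calcium handling and ion channels, 21 were marked (adjusted exact p = 0.00692), with Sln, the small regulator of the calcium pump of the sarcoplasmic reticulum, without a peak in either replicate. The 26 genes of heart development signalling were all marked (adjusted exact p = 0.00034). Among the other cell types of the heart, all 20 endothelial and endocardial genes were marked (adjusted exact p = 0.00103), as were 17 of 18 genes of epicardium and mesenchyme (adjusted p = 0.0161). Upk3b, an epicardial surface protein, was the exception there, although each replicate list had a peak at its start site. Of the smooth muscle and pericyte genes 14 of 15 were marked, which missed the threshold (adjusted exact p = 0.0544), with Actg2, the enteric smooth muscle actin, marked in replicate 2 and the pooled list but not in the replicated list. All 21 cell cycle genes (adjusted exact p = 0.00103) and all 24 housekeeping genes (adjusted p = 0.000398) were marked. Against genes of the same CpG content the cell cycle and housekeeping lists no longer passed (adjusted exact p = 1.0 and 0.0525). With all members of both lists marked, no higher share was possible. The matched test could therefore not have passed them as higher, and it does not show that CpG content accounts for their marking. With the stronger part of the peaks the epicardial list did not pass (adjusted exact p = 0.146). The smooth muscle list passed with CpG matching (adjusted exact p = 0.0218), the pooled list (0.0108), −log10 q of at least 5 (0.0327), the outermost 5′ end (0.0202) and the own summit nearest (0.0131).

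Germ line, skeletal muscle, blood and olfactory receptor genes were marked less often than other genes in the replicated list. Of the 18 genes of pluripotency and germ line 5 were marked (adjusted exact p = 0.00103). Ddx4, the germ-cell helicase, had a peak in replicate 1 alone, and Dppa3 in the pooled list alone. Skeletal muscle genes were marked at 7 of 20 (adjusted exact p = 0.00492), with Chrna1, a subunit of the muscle acetylcholine receptor, unmarked in every list. Acta1, the skeletal actin, was without a replicated peak, although each replicate list and the pooled list had a peak at its start site. Blood genes were marked at 8 of 20 (adjusted exact p = 0.0179), and some of those without a replicated peak had one in another list. Among these, Alas2, the erythroid enzyme of haem synthesis, had one in replicate 1, and Cd68, a macrophage glycoprotein covered over 3986 bp within 5 kb, in replicate 2 and the pooled list. Of 1135 olfactory receptor genes 5 were marked (0.441% against 71.5% of other genes). Neural and neural crest genes, at 13 of 20, did not pass the test (adjusted exact p = 0.812), and neither did the endoderm list at 9 of 19 (adjusted p = 0.0866), in which Afp and Alb, secreted proteins of the liver, had no covered base within 5 kb in any replicate. Both lists passed as lower in the stronger part of the peaks (6 of 20, adjusted exact p = 0.00223, and 5 of 19, 0.00157), and the endoderm list also with −log10 q of at least 5 (0.0327) and with the outermost 5′ end (0.0115). The neural share turned higher than that of other genes, without passing, by 20.7 points with the 2.5 kb window, 5.39 with replicate 1 alone, 1.56 with the own summit nearest and 0.0119 in the pooled list. The lower shares of the blood and skeletal muscle lists rested on the list used. With replicate 1 alone they were at 12 and 10 of 20 (adjusted exact p = 0.36 and 0.0953), with replicate 2 alone both were at 9 of 20 (adjusted p = 0.0544 for each), and neither passed with CpG matching (adjusted p = 0.415 and 0.149), where the blood share was 8.90 points higher than in matched genes.

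The Hox genes pattern the body axis, and the anterior and posterior paralogues listed here differed in how often they were marked. Paralogues between these groups were in no list. Anterior paralogues were marked at 14 of 15 genes and posterior paralogues at 3 of 16. A direct Fisher's exact test of this difference, not among the tests fixed in advance, gave p = 3.85e-05. Neighbouring Hox genes of a cluster can share peaks, so they are not independent and the p-values of this paragraph may be too small. Replicate 1 gave 15 of 15 and 5 of 16 (p = 6.77e-05, exact) and replicate 2 gave 14 of 15 and 5 of 16 (p = 0.000635, exact). Hoxb1 was the unmarked anterior gene of the replicated list and had a start-site peak in replicate 1 and in the pooled list. Hoxd13, Hoxd9 and Hoxa13 were the marked posterior genes, with folds of 3.68, 3.89 and 2.71; Hoxa13 was chosen after its values were seen. Hoxa10, with a peak in replicate 1 alone, and Hoxa11, with none in any list, were among the unmarked posterior genes. Against all other genes the posterior list was lower (adjusted exact p = 0.00034) and the anterior list missed the threshold (adjusted p = 0.0544), which it passed with replicate 1 alone (0.0116), the pooled list (0.0108) and −log10 q of at least 5 (0.0327). Its direction turned in the stronger part of the peaks (−4.90 points, adjusted exact p = 0.788) and with the own summit nearest (−5.11 points, 0.842).

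**Figure D2:**
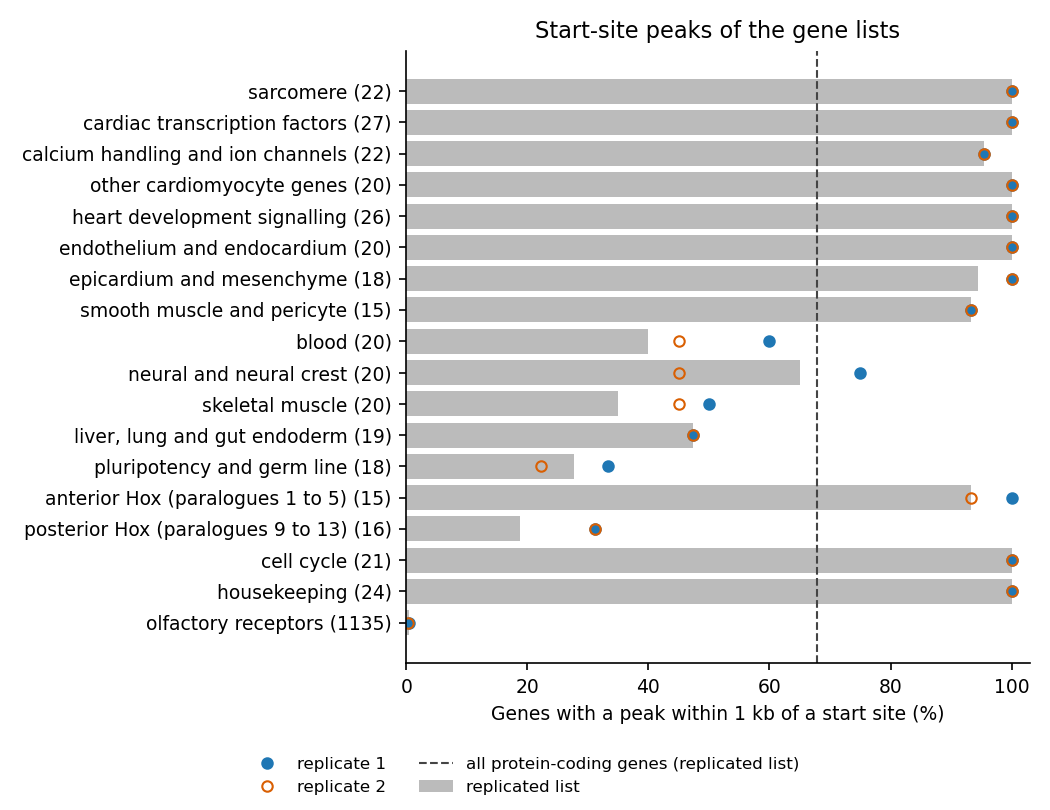
Share of the members of each fixed gene list (%) with a peak within 1 kb of a start site in the replicated list and in each replicate list. The heart muscle lists lie at 95.5% or above, posterior Hox genes at 18.8% and olfactory receptors at 0.441% in the replicated list.

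The fourth comparison asks how many bases around the start site lay under peaks. These bases can belong to several peaks, also of neighbouring genes, and need not form a single stretch. Among the genes with the longest covered lengths, 4 were of the cardiac transcription factor list (Gata4, Gata6, Tbx5 and Meis1). A further 1 was of the sarcomere list (Myh7) and 5 were of no list. Gata4, the zinc-finger factor of cardiac progenitors, lay under the widest replicated peak of the genome, 20791 bp on chromosome 14 from 63236461 to 63257251, with a fold of 38.6. Gata6 (chromosome 18, 11046811 to 11058265, fold 37.2), Tbx5, the T-box factor mutated in Holt-Oram syndrome (chromosome 5, 119828716 to 119844014, fold 25.9), and Myh7, the slow myosin heavy chain (chromosome 14, 54981052 to 54996895, fold 24.6), were covered over the whole 10001 bp window in both replicates. So were Nfib, a nuclear factor I protein (chromosome 4, 82498933 to 82510449, fold 42.4), and Meis2, a homeobox cofactor. Smad7, an inhibitor of TGF-beta signalling, Meis1, Kdm6b, a histone H3K27 demethylase, and Igf2, a fetal growth factor, were covered over the whole window in the replicated list and over 9846 ± 116, 9950.5 ± 71.4, 9665 ± 63.6 and 9921 bp ± 0 in the replicates (SD, n = 2). In all, 11 genes filled the window, so their order there is set by the tie rule.

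By list, cardiac transcription factors had a median covered length of 8119 bp (7219 ± 511 in the replicates, SD, n = 2) and sarcomere genes of 8097.5 bp (7459.8 ± 243). Both lay above all 10000 random lists, and the median of all protein-coding genes was 1716 bp. Covered length was taken at the start site with the most, so genes with more annotated start sites had more chances of a long one. Random lists were not matched on the number of start sites of a gene, and what this adds to the covered lengths was not tested. Tpm1, alpha-tropomyosin, was covered over 9902 bp (9533 ± 346.5). Genes of calcium handling and ion channels had 5007 bp (4600.2 ± 170), with 7671 bp at Slc8a1, the sodium-calcium exchanger, and 7561 bp at Cacna1c, the L-type calcium channel, whose strongest summit was nearer to Dcp1b. Other cardiomyocyte genes had 5462 bp (4772.5 ± 39.6), led by Rbm20, a splicing factor of titin, with 8369 bp (8405.5 ± 248). Eno3, the muscle enolase, followed with 7920 bp, and its strongest summit was nearer to Pfn1. Signalling genes had 5013.5 bp (4543.8 ± 159), with 7742 bp at Vegfa and 7041 bp at Notch1. Endothelial genes had 4092.5 bp (3633 ± 433), with 8652 bp at Egfl7 and 7684 bp at Nfatc1, the factor of endocardial cushion and valve formation. Epicardial and mesenchymal genes had 3613.5 bp (3306.8 ± 206; percentile 99.9), with 8624 bp at Wt1, the epicardial zinc-finger factor, and 8518 bp at Pdgfra. Smooth muscle and pericyte genes had 2795 bp (2565.5 ± 182), within the range of random lists (percentile 96.0; above it at 99.4 with CpG matching and 97.9 within 10 kb), with 7233 bp at Cspg4 and 5750 bp at Smtn. Cell cycle genes had 3677 bp (3503.5 ± 402) and housekeeping genes 4242.5 bp (3842.5 ± 465), both at percentile 100, with 9273 bp at Ccnd2 (strongest summit nearest to 9330179D12Rik) and 7350 bp at Ccnd1, and with 8644 bp at Gapdh and 8194 bp at Hmbs (strongest summit nearest to Gm44335). The strongest start-site peak was 3142 bp wide at Ccnd2 and 2357 bp at Gapdh, so these lengths rest on more than a single peak.

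Posterior Hox, germ line and olfactory receptor genes lay below random lists in covered length. Posterior Hox genes had a median of 0 bp (45.8 ± 64.7 in the replicates, SD, n = 2; percentile 1.02), germ line genes 0 bp (41.2 ± 58.3; percentile 0.845) and olfactory receptors 0 bp. Skeletal muscle genes had 443 bp (261 ± 89.1; percentile 3.64), endoderm genes 581 bp (341 ± 99; percentile 5.72), neural genes 686.5 bp (601.8 ± 342; percentile 6.28) and blood genes 1013 bp (859 ± 513; percentile 12.4), all within the random range. Skeletal muscle genes lay below it in replicate 1 alone (percentile 2.46), in replicate 2 alone (2.33) and with −log10 q of at least 5 (1.0), and endoderm genes did among marked genes only (1.46). Anterior Hox genes had 2220 bp (2026 ± 291; percentile 79.5, and 99.7 within 10 kb), led by Hoxb3 with 7502 bp, where the strongest summit was nearest to Gm11536, and Hoxa2 with 7480 bp. Single genes of these lists were covered far: Tal1, the factor of blood and endothelial progenitors, over 7726 bp (7417.5 ± 445) with a fold of 11.2, and Slc4a1, the red cell anion exchanger, over 6063 bp (5102.5 ± 2456) with a fold of 5.07. Mylpf, a fast skeletal myosin light chain, had 5979 bp and Sftpc 4353 bp, and their strongest summits were nearer to Tbc1d10b and Bmp1. Tnni2, the fast skeletal troponin I, had 3972 bp, Foxa2, an endoderm factor, 2707 bp, and Phox2a, an autonomic neuron factor, 2671 bp. Dbh, the enzyme of noradrenaline synthesis, had 2559 bp within 5 kb and no start-site peak. Tdrd1 and Tex14, germ-cell genes, had 2065 and 1886 bp, and the Tex14 summit was nearer to Rad51c. Olfr94 had 1033 bp, the most of any olfactory receptor gene. Against random lists of the same CpG content, blood genes stood at percentile 99.5, above the range, and neural genes at 0.02, below it, as they did among marked genes only (0.07).

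**Figure D3:**
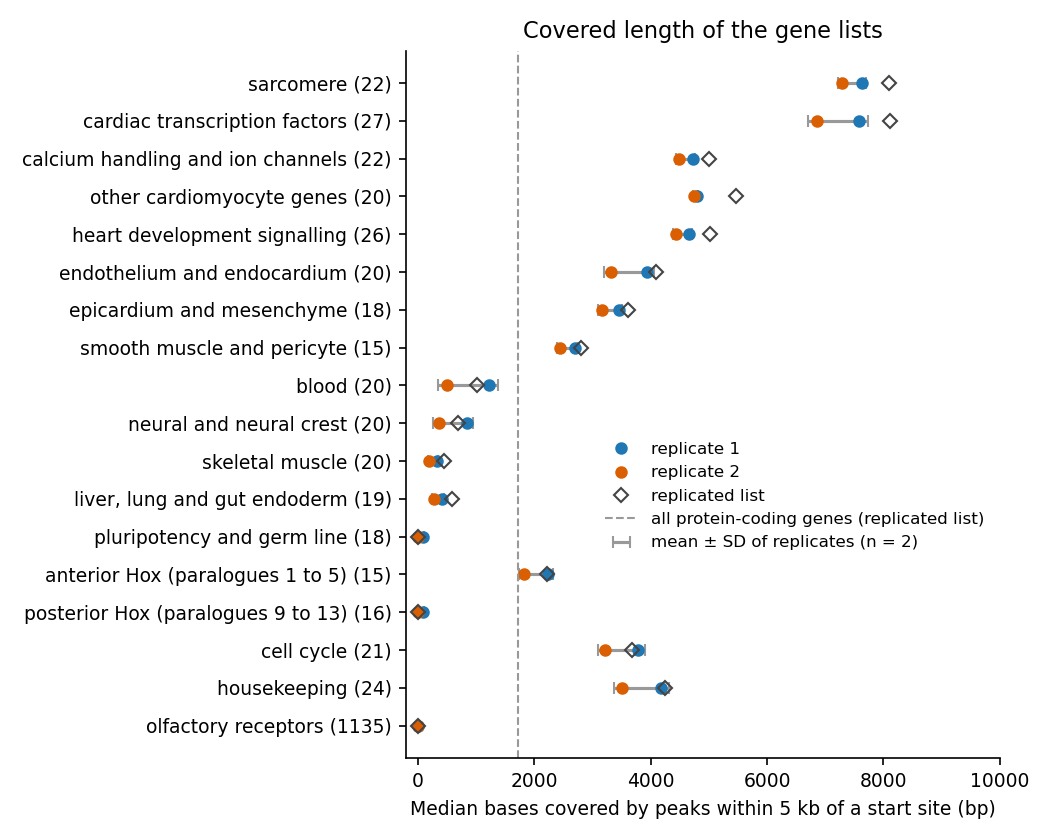
Median bases covered by peaks within 5 kb of a start site (bp) for each fixed gene list, in the replicated list and in each replicate list, beside the median of all protein-coding genes, with bars for the mean ± SD of the replicates (n = 2). Cardiac transcription factors (8119 bp) and sarcomere genes (8097.5 bp) lie highest in the replicated list, against 1716 bp for all genes.

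Of the 10 genes with the strongest start-site peaks, Hand2 belonged to the cardiac transcription factor list, Ywhaz to the housekeeping list and the others to no list. Actg1, cytoplasmic gamma-actin, Hnrnpu, an RNA-binding nuclear protein, and Ywhaz, a 14-3-3 protein, shared the highest fold at a protein-coding start site, 42.9. Hand2, the basic helix-loop-helix factor of the right ventricle, followed with 42.8, in a peak on chromosome 8 from 57316403 to 57330892 whose summit was nearest to its divergent transcript Hand2os1. Adnp and Atf4, the factor of the amino acid response, had 42.7, Nfib 42.4, Ubtf, the RNA polymerase I factor, 42.1, Ptma 42.0 and Sfpq 41.9. Nfib was the gene common to this group and the group with the longest covered lengths. Covered lengths of this group ranged from 3566 bp at Adnp to 10001 bp at Nfib.

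The fifth comparison asks which genes had H3K9ac peaks away from start sites. Sarcomere genes had a median of 10 distal peaks within 50 kb, cardiac transcription factors 8, calcium handling and ion channel genes 8, other cardiomyocyte genes 5.5, smooth muscle genes 5, endothelial genes 4 and signalling genes 3.5. These 7 lists lay above random lists, whose median was 1. Peaks were counted around all start sites of a gene, so genes with widely spread start sites were searched over a longer stretch. Random lists were not matched on the length of this stretch. How much of the excess of the 7 lists comes from longer stretches was not tested. The lists of replicate 1 and replicate 2 gave higher medians: 18 and 15 for sarcomere genes, 13 and 14 for cardiac transcription factors, 13.5 and 10.5 for calcium handling and ion channels, 11 and 7.5 for other cardiomyocyte genes, 8 and 6 for smooth muscle, 7.5 and 5 for endothelial and 9.5 and 6 for signalling genes. Random lists of those sizes had medians of 3 in replicate 1 and 1.5 to 2 in replicate 2, and the 7 lists lay above them in both. Rbm20 had 52 distal peaks (75 ± 9.90 in the replicates, SD, n = 2), Cacna1c 40 (61.5 ± 9.19), Notch1 22 (40.5 ± 3.54), Smad7 25 (40 ± 1.41), Gata4 18 (28.0 ± 0) and Tpm1 17 (25 ± 14.1). Epicardial, cell cycle, housekeeping and endoderm genes had a median of 2, germ line genes 3 (percentile 95.9), blood genes 1.5, skeletal muscle and posterior Hox genes 1, neural genes 0.5 and anterior Hox genes 0, all within the random range. Olfactory receptors had a median of 0, below it. Within 100 kb signalling (percentile 95.9), endothelial (96.2) and smooth muscle genes (96.9) fell back into the range, which left 4 lists above. So did endothelial genes in the pooled list (97.4) and, with −log10 q of at least 5, smooth muscle genes (70.7) and olfactory receptors (22.9).

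The strongest distal peak of the replicated list lay on chromosome 8 from 69715322 to 69716973, between genes, 4598 bp from the nearest protein-coding start site (Zfp869), with a fold of 31.7. The next lay on chromosome 7 from 73618589 to 73619615, 76759 bp from Chd2 (fold 28.0), and on chromosome 12 from 8640751 to 8641728, 32406 bp from Pum2 (fold 27.6). A peak of 26.8-fold on chromosome 15 from 85668915 to 85673338 lay in an intron of the non-coding gene Lncppara, 61645 bp from Ppara. A peak of 25.3-fold on chromosome 16 from 96158277 to 96160423 overlapped with its summit an exon of Lca5l, 6467 bp from Wrb.

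The sixth comparison asks how the mark was distributed over the chromosomes. Chromosome X carried 987 replicated peaks, 5.77 per Mb, against 19.6 per Mb on chromosome 3, the lowest autosome, and 49.5 per Mb on chromosome 11, the highest (median of the autosomes 28.8). Per protein-coding gene X had 1.04 peaks against 2.34 to 4.28 on the autosomes (median 3.24). Of the X genes 50.2% were marked, against 56.8 to 79.9% on the autosomes. The 476 marked X genes had a mean of 0.395 distal peaks against 2.58 to 5.29, and a median fold of their strongest start-site peak of 10.4 against 15.2 to 18.2. Over all replicated peaks, of which 18.9% were distal on X and 51.8% on the autosomes, the median fold was higher on X (6.00 against 3.39), as it was in each replicate list and the pooled list. The Y chromosome carried 4 peaks. Replicate 1 had 1.27 to 1.34 times as many peaks as replicate 2 on each autosome and 1.03 times as many on X. The replicate lists held 7.26 and 7.05 peaks per Mb on X, and their autosome medians were 50.2 and 37.5, so the step between X and the autosomes was larger than the spread between replicates.

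**Figure D4:**
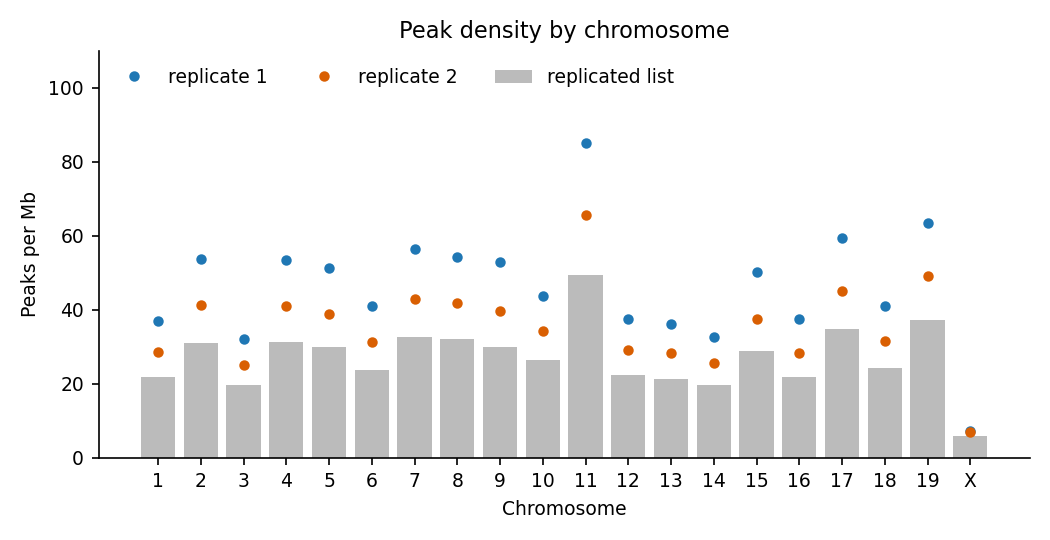
Peaks per Mb of each chromosome in the replicated list and in each replicate list. In the replicated list chromosome X stands at 5.77 per Mb and the autosomes between 19.6 and 49.5.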

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

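Among the tests below, the one on strong sites of a single embryo pool and the counts of CpG-rich genes were chosen only after the result was seen. Actn3, Mpz, Pou5f1 and Hba-x are named below outside the rule for named genes. Peaks on scaffolds not placed on a chromosome are a signal outside the comparisons above: each list held 9, including the replicated list, with replicated folds of 1.69 to 13.3. The design holds 1 group, so biological explanations were tested only where a value of these lists bears on them.

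Replicate 1 had more peaks than replicate 2, and its unpartnered peaks were weak and narrow (median fold 2.86, median width 214 bp). Random weak calls spread evenly over the chromosomes are argued against for replicate 1. Of its unpartnered peaks, 70.1% lay within 5 kb of a replicate 2 peak against 18.8% under random placement, 3.74 times as many. Replicate 2 gave a like excess, with 78.6% of its unpartnered peaks near a replicate 1 peak against 22.4%. The placement was even over each chromosome, so weak calls that gather in regions rich in peaks stay open. Strong sites present in only one embryo pool are argued against for the strongest of 10 rank bins of replicate 1 alone, where 0 peaks lacked a partner, a value already given above; in bin 2, where 98.1% had one, and in weaker bins, sites of a single pool stay open. A difference between the further input files of the lists stays open, because the ratio of 1.30 cannot be recomputed with exchanged files without the reads; depth, which is unknown, stays open and untested as well.

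Chromosome X had few peaks, most of all away from start sites. Fewer marked X genes do not account for this, since marked X genes had 0.105 times the mean number of distal peaks of the median autosome. Repeat content is argued against by a ratio of 0.128 (95% bootstrap interval 0.0979 to 0.166) to autosomal genes of the same repeat share. The bootstrap drew single X genes, and neighbouring genes can count the same distal peaks, so this interval is likely too narrow. The folds of the strongest start-site peaks of marked X genes were 0.710 times those of autosomal genes of the same CpG bin (0.678 to 0.747), which is consistent with fewer active copies of chromosome X per cell. Fewer X copies in the DNA of mixed-sex pools could give the same ratio; neither was tested for the size of the distal deficit, and over all replicated peaks, few of them distal on X, the median fold was higher on X (6.00 against 3.39).

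Start-site peaks lay at 42 of 97 genes of the blood, neural, skeletal muscle, endoderm and germ line lists. Of all protein-coding genes, 67.9% were marked. A neighbouring gene's peak is argued against as the general source, since 14.3% of these genes (6 of 42; exact 95% interval 5.43 to 28.5) had their strongest summit nearer to another gene, against 13.9% of all marked genes; the 6 were Actn3, Mpz, Mylpf, Pou5f1, Sftpc and Tex14. Weak peaks at CpG-rich start sites stay open: the median fold was 0.444 times that of marked genes of the same CpG bin. Its bootstrap interval (0.350 to 0.549) spans the bound of 0.5 set in advance. A CpG ratio above that of the median gene was found at 20 of the 42 marked and 9 of the 55 other members. The ratio was taken at the outermost 5′ end of each gene, which need not be its marked start site. Red blood cells in the dissected hearts stay open: 6 of 13 erythroid genes of the blood list were marked, fewer than the 7 set in advance, and of the 5 globin genes only Hba-x was. Replicate 1 marked 9 of the erythroid genes and replicate 2 marked 5.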

How the results depend on the processing

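The alternatives without assembly gaps and with the summit nearest to the own start site were chosen after seeing the data. No paired analysis was possible because the series holds 1 group. Unless a reason is given, the cause was not tested. Start sites by replicate kept all 9 values within 1.5 times. Over the lists, 130 of 162 start-site results kept direction and side of the threshold, 12 came to pass it, 13 no longer did and 7 reversed; of 126 covered-length results 115 kept both, 9 came to pass and 2 reversed; of 108 distal results 96 kept both, 6 no longer passed and 6 reversed. Replicate overlap (replicate 1, replicate 2, shared bases) asks for more by construction with 50% of both peaks (34.5%, 44.8%) and 50% of the peak (39.6%, 62.0%); it was 68.8%, 89.4% and 69.7% with −log10 q of at least 5, 58.3%, 80.9% and 63.7% in the stronger part of each list, and 59.7%, 66.0% and 57.8% with equal numbers. With 50% of the replicated peak, overlap was 79.0% by replicate 1, 65.0% by replicate 2, 53.2% by both and 9.20% by neither. Summits at start sites, in exons, in introns and between genes made up 25.3%, 6.41%, 47.8% and 20.5% in the pooled list, 46.8%, 3.52%, 33.5% and 16.2% with the wider 2.5 kb window, 43.9%, 5.09%, 34.5% and 16.5% with −log10 q of at least 5, and 55.4%, 4.40%, 25.6% and 14.6% in the stronger part. Leaving out each replicate in turn gave 27.0 to 32.6% at start sites, 5.80 to 6.36% in exons, 43.4 to 46.8% in introns and 18.3 to 19.8% between genes, 7.05 to 7.26 peaks per Mb on X, 37.5 to 50.2 on the median autosome, and 1.27 to 1.31 and 4.21 to 5.54 peaks per gene. In the pooled list these were 7.37 and 51.1 per Mb, and 1.33 and 5.75 per gene. The number of lists lower at start sites was 3 without each replicate, in the pooled list, with 2.5 kb and with CpG matching, against 5, and 4 with the own summit nearest, 6 with the outermost 5′ end and with −log10 q of at least 5, and 7 in the stronger part; lists below in covered length numbered 5 among marked genes only, against 3; distal lists above numbered 4 within 100 kb, against 7, and distal lists below 0 with −log10 q of at least 5, against 1. The neural list, −2.85 percentage points from other genes, reversed: −23.0 to 5.39 on leaving out each replicate (5.39 without replicate 2), 0.0119 in the pooled list, 20.7 with 2.5 kb and 1.56 with its own summit nearest; it went further down to −9.30 with the outermost 5′ end, −11.3 with CpG matching, −21.6 with −log10 q of at least 5 and −34.9 in the stronger part, where it passed the threshold. Anterior Hox genes turned to −4.90 in the stronger part and −5.11 with the own summit nearest, and blood to 8.90 with CpG matching. With CpG matching the percentile of covered length turned to 99.5 for blood; the 50 of olfactory receptors there is a tie at 0 bp with the matched lists, which no list can lie below, and decides nothing. Percentiles of distal peaks ranged from 11.2 to 92.4 for blood and 64.2 to 75.9 for skeletal muscle on leaving out each replicate; skeletal muscle stood at 71.7 in the pooled list and 56.9 within 100 kb, and posterior Hox genes at 74.2 with −log10 q of at least 5. The percentiles near the middle rest on medians of few peaks. The depth is unknown, so what it limits could not be assessed; 70.6% of replicated peaks reached a −log10 q of 5.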

Other observations

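The genes of the paragraphs below were chosen after their values were seen. Casz1, a zinc-finger factor of heart muscle development, had the most distal replicated peaks within 50 kb of its start sites of any protein-coding gene, 87 (117.5 ± 2.12 in the replicates, SD, n = 2), or 38.0 per 100 kb searched. Zmiz1 followed with 79 (117 ± 4.24), Gse1 with 73, Mical2, an actin-oxidising enzyme, with 68, Tspan9 with 66, Prdm16, a chromatin regulator, with 61 and Rbfox2, a splicing factor, with 58. Tead1, a nuclear partner of the Hippo pathway, had 47. The median gene had 1, and 41.4% of genes had none. The searched stretch grows with the spread of a gene's start sites: Kalrn had 51 distal peaks but 7.34 per 100 kb, against a median of 0.99 over all genes. On chromosome X, Bcor, a Polycomb-associated corepressor, had 19 distal peaks (28.5 ± 7.78), Nhsl2 was next with 7, and 86.0% of the 948 X genes had none. The longest covered lengths of X lay at Tmem164 (6605 bp), Flna, the actin crosslinker filamin A (6376 bp), and Efnb1 (5948 bp).

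Families of genes that share a symbol stem differed in covered length. The Klf zinc-finger factors (17 genes) had the longest median, 4214 bp (4206 ± 448 in the replicates, SD, n = 2), followed by the histone genes (67 genes, 4207 bp, 3976 ± 298). Zbtb factors (41 genes) had 3454 bp (3385.5 ± 336) and ribosomal proteins of the Rpl stem (54 genes) 3446 bp (3301.5 ± 321). The Vmn vomeronasal receptors (331 genes) had a median of 0 bp, with 0.302% of members marked, and keratins and the Pcdhb protocadherins also had 0 bp. A symbol stem alone does not show a shared function. Within that limit, the hypothesis that families of shared function have longer or shorter covered lengths than other genes may hold. Of 151 families, 52.3% (36 above and 43 below) lay outside the range of random lists of their size. With random lists matched on CpG content 15 lay above, 14 of which were among the 36, so most families above the first range were not above the matched one. Most families below the first range had a median of 0 bp, and where the matched lists also had 0 bp no family could lie below them, so the 6 below there are not set against the 43. Genes of a family in tandem clusters share windows, so their values are not independent.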
